A study of Arabidopsis thaliana with 2 samples.

How the data were processed

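DNA methylation was measured by whole-genome bisulfite sequencing of 12-day-old Arabidopsis thaliana seedlings of ecotype Col-0. There were 2 libraries, 1 of the wild type and 1 of the xrn3 single mutant. Bisulfite turns unmethylated cytosine into uracil, which is read as T, and leaves methylated cytosine as C. Per the labels' protocols, DNA was sonicated, ligated to methylated adaptors and converted with a commercial kit. The submitters' processing notes name fastp 0.20, BSMAP and the genome build TAIR10. The version and options of BSMAP, and any removal of duplicate reads, are not given in the sources used here.

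For each cytosine, the deposited tables hold the count of reads with C, the count of reads with C or T, and the counts of opposite-strand reads with G and with G or A, per the file headers. They also hold an estimated count of reads, which the authors corrected by the opposite strand, and the methylation level as a fraction with its bounds. A test on every row showed that the authors' estimated count equals the read count times the share of G among opposite-strand reads, within 0.006 reads apart from number precision. The deposited fraction equals the methylated count over that estimated count, capped at 1, within 0.01 in 100% of rows of both tables. No row with opposite-strand reads has none with G, so a cytosine replaced by T in a line is left out of that line's table. The counts of C and of C or T were used for all main results, the estimated counts (rounded to whole numbers) for an alternative, and the deposited fraction and its bounds for no result.

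A cytosine entered when it had at least 4 reads in both libraries, which left 41403002 of 42830471 nuclear cytosines listed in either table (96.7%). Mean depth was 21.3 reads per nuclear cytosine in the wild-type library and 16.3 in the xrn3 library. Levels are methylated reads over all reads, pooled over the cytosines of a region, so deeper cytosines weigh more. A read counts once for each cytosine it covers, so read numbers of regions and windows exceed the numbers of sequenced reads. Differences are xrn3 minus wild type in percentage points. Errors of differences are standard errors from a jackknife that leaves out 1 Mb blocks of the genome in turn, with intervals of 1.96 standard errors. They describe the spread along the genome and not the spread between plants. Exact (Clopper-Pearson) 95% binomial intervals cover counting error only, since reads carry no molecular identifiers. They treat the cytosines of a read as independent and are too narrow. With 1 library per group there was no replicate check, and every test compares the 2 libraries, not the genotypes.

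Windows of 100 bp with at least 4 cytosines of a context were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within the context. A window was called at an adjusted p under 0.01, a difference of at least 40 (CG), 20 (CHG) or 10 (CHH) points and the same sign on both strands. Gene bodies and 1 kb flanks with at least 5 cytosines were tested in the same way at 20, 10 and 5 points. Cytosines on the same read are not independent, so these p-values are too small. As a control, the strands of 1 library were tested against each other without the sign rule. The p-values of window locations treat neighbouring windows as independent and are also too small.

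Gene names and spans came from the RefSeq gene table of assembly TAIR10.1, which holds 27444 protein-coding genes, 4843 pseudogenes (a class that includes transposable element genes) and 5612 non-coding RNA genes on the 5 nuclear chromosomes. Its build name differs from that of the files. The frame was therefore tested on the data: the end base of the gene spans was C in 20.7% to 21.8% of genes by chromosome, against at most 18.8% to 19.8% at other positions within 10 bp. Coordinates are printed as the deposited files give them. The gene table gives no strand. The strand of 11384 protein-coding genes (41.5%) was inferred from the pattern of C and G along the gene with a hidden Markov model at a log-likelihood ratio of at least 15. In 1566 held-out genes whose parts both passed that limit, the parts gave the same strand in 96.7%, an implied error of 1.66% per part. Genes with an inferred strand were longer (median 2841 bp against 1586.5 bp). Transposable elements without a gene entry were not analysed here as a class.

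Pericentromeric intervals were fixed as 12 to 18 Mb of chromosome 1, 1 to 7 Mb of chromosome 2, 11 to 17 Mb of chromosome 3, 2 to 6 Mb of chromosome 4 and 9 to 15 Mb of chromosome 5. Body-methylated genes had a mean over both libraries of at least 20% CG and under 5% CHG and CHH. Named genes were XRN3, members of 6 gene lists with a called region and the 3 members per list with the largest absolute difference in any context or region, and, for each context and direction, the 3 protein-coding genes and the 1 pseudogene with the largest called difference. Candidate sequence variants were cytosines with at most 10% G among at least 10 opposite-strand reads in 1 library and at least 90% in the other. Coverage differences were runs of at least 3 windows of 1 kb with a log2 ratio of scaled coverage beyond 1 either way. The tests, thresholds, gene lists and intervals were fixed before the data were examined, except for the limits that class body-methylated genes, the inference of strand, the measure of the drop in coverage at XRN3, the tests of explanations in the closing section, and the use of pseudogenes in place of transposable element genes in the naming rule.

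Alternatives changed the coverage minimum to 1 or 10 reads, weighted cytosines equally, subtracted the chloroplast rate, used the estimated counts, thinned the deeper library, left out cytosines with under 90% G opposite or above 5 times the median coverage, used 200 bp windows or 500 bp flanks, dropped the strand rule, halved the size thresholds to 20, 10 and 5 points, lowered the adjusted p to 0.001, took 500 bp downstream of 3′ ends, kept only genes with no other gene within 1 kb downstream, and changed the limits of the variant and coverage rules. Backgrounds for window locations with room for the difference or matched on mean level in steps of 5 points, and variants found as sites absent from 1 table, were added after seeing the data.

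The steps were tested on simulated data drawn at the real depths and mean levels, with 200 changed units each. Of 200 changed windows, 197 were recovered in CG (677377 windows), 152 in CHG (733352 windows) and 168 in CHH (1184269 windows), with 0 calls among unchanged windows. At true differences of 25 points in CHG, 54.4% of changed windows were recovered, and at 12.5 points in CHH 73.5%. Of 200 changed gene regions, 197 were recovered in CG, 179 in CHG and 198 in CHH, and 0 unchanged regions were called. Simulated reads were independent, unlike real ones. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.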

Results

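The series concerns transcription termination, and this part of it compared DNA methylation between seedlings of the wild type and of the xrn3 mutant of Arabidopsis thaliana. XRN3 is a nuclear 5′ to 3′ exoribonuclease that degrades the RNA left on RNA polymerase II after transcript cleavage. Whole-genome bisulfite sequencing gave methylation in the CG, CHG and CHH contexts (H is A, C or T), which plants maintain by different enzymes. There was 1 library per genotype, from 12-day-old seedlings. Reads summed over nuclear cytosines, each counted once per cytosine it covers, numbered 913397311 in the wild-type library and 698153246 in the xrn3 library. Read numbers beside the levels of regions and windows are counted in the same way. With no replicates, none of the differences given here could be set against a spread between plants.

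At XRN3 (AT1G75660; cytosines 28408137 to 28415117 of chromosome 1, TAIR10) the libraries had nearly the same level pooled over the whole gene. The CG level was 29.0% in the wild type (exact 95% binomial interval 27.8 to 30.1, 5941 reads) and 29.99% in xrn3 (28.6 to 31.4, 4178 reads). Parts of the gene differed in CG both ways, with 51.1% against 29.1% in the 500 bp from 28410001, 37.9% against 57.0% in the 500 bp from 28410501 and 44.7% against 26.5% in those from 28411501. CHG and CHH levels lay at the background of unconverted cytosines, with CHG at 0.795% and 1.01% and CHH at 0.957% and 0.9503%. Mean coverage per cytosine was 21.0 reads in the wild type and 15.3 in xrn3. In the xrn3 library, coverage of both strands dropped to 4 reads at position 28408246, near the lower-coordinate end of the gene, where the median along the gene was 33. The lowest value in the wild type was 14 reads, at position 28414626. In the 100 bp window from 28408201 to 28408300, coverage was 13.4 reads in xrn3 and 58.1 in the wild type, a log2 ratio of -1.70 after scaling by library depth, a measure chosen after the coverage of the gene had been seen. The next lowest of the 71 windows of the gene had a log2 ratio of -0.50. Of 1174238 windows in the genome, 467 (0.0398%) were as low in xrn3, and 156 were as low in the wild type.

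CHH methylation was lower in the xrn3 library genome-wide. It was 3.99% in the wild type and 3.78% in xrn3, a difference of -0.211 points (jackknife SE 0.0329, interval -0.275 to -0.146). The pooled CG level was 29.6% in the wild type and 30.2% in xrn3 (difference 0.666, SE 0.0914), and the CHG level was 11.7% and 11.9% (difference 0.211, SE 0.0332). The CG and CHG differences changed sign when every cytosine was given the same weight, to -0.319 (SE 0.0241) and -0.330 (SE 0.0516), and the CHH difference became -0.311 (SE 0.0368). With at least 10 reads per cytosine the CHG difference was 0.105. Pericentromeric cytosines took 25.4% of the nuclear reads in the wild type and 26.4% in xrn3. In the chloroplast genome, which is unmethylated and measures incomplete conversion, 0.622% of CG, 0.847% of CHG and 0.913% of CHH reads were unconverted in the wild type. The xrn3 library gave 0.617%, 0.848% and 0.939%.

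In points, the CHH difference was larger around the centromeres than in the arms. In pericentromeric intervals CHH methylation was 9.44% in the wild type and 8.54% in xrn3, a difference of -0.905 points (SE 0.0746). In the chromosome arms it was 2.09% and 2.04%, a difference of -0.0487 points (SE 0.00795). With the chloroplast rate subtracted, CHH was 8.61% against 7.67% in pericentromeres and 1.19% against 1.11% in the arms (differences -0.937 and -0.0750). The difference in the arms was -0.109 points with equal weights per cytosine. CHG in pericentromeres was also lower in xrn3 (35.9% against 35.0%, difference -0.967, SE 0.342), while the interval of the CG difference there included 0 (-0.334, interval -1.53 to 0.865). With equal weights per cytosine the pericentromeric CG difference was -0.604 (SE 0.0691). In the arms the pooled CG and CHG levels were higher in xrn3, by 0.257 points (SE 0.0418) and 0.168 points (SE 0.0129), and both differences changed sign with equal weights per cytosine (-0.232 and -0.0632). CHH was lower in xrn3 in 103 of 121 blocks of 1 Mb, with block differences from -1.33 to 0.0425 points.

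**Figure D1:**
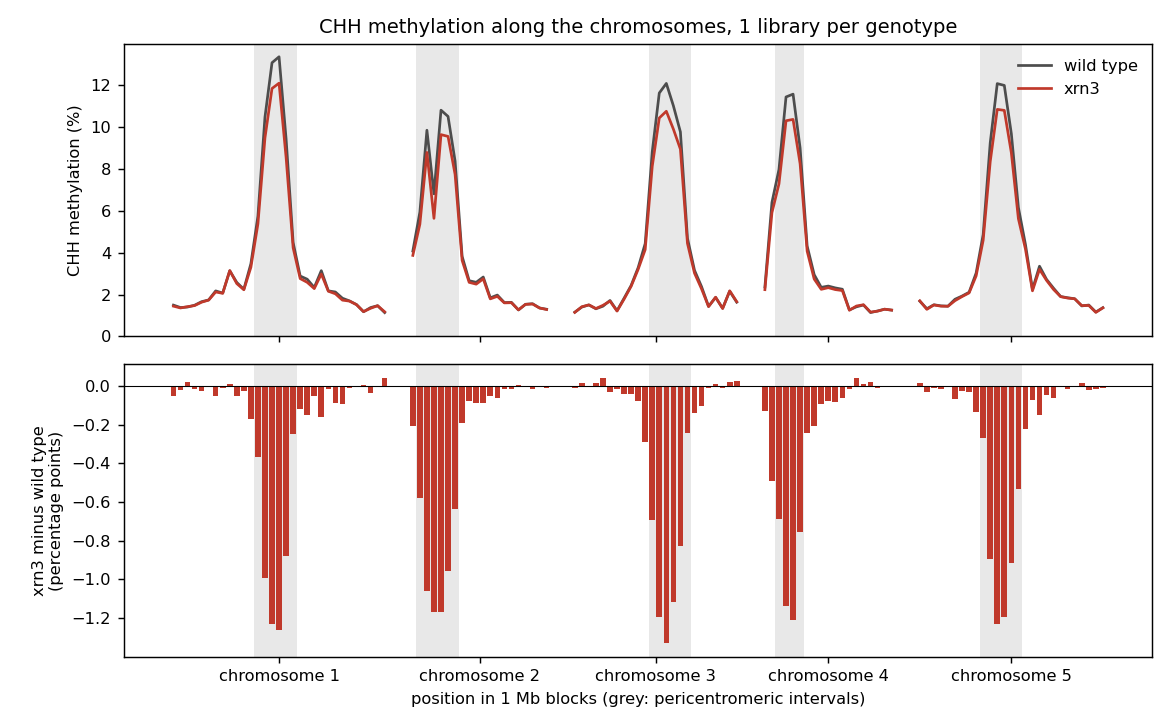
CHH methylation in percent in 1 Mb blocks along the 5 chromosomes in the wild-type (grey) and xrn3 (red) libraries, and below it the difference in percentage points as bars, with 1 library per genotype and no error bars. The difference reaches -1.33 points in the shaded pericentromeric intervals and -0.491 points in a block beside one of them.

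Among gene classes, pseudogenes, which here include transposable element genes, had lower CHH methylation in xrn3, and lower CHG methylation around the centromeres. Pooled levels of all protein-coding gene bodies were nearly the same in both libraries. Their CG level was lower in xrn3 with equal weights per cytosine. Pseudogene CHH was 11.7% in the wild type and 10.8% in xrn3 (difference -0.916, SE 0.0420), and 82.3% of 4836 pseudogenes were lower in xrn3. Pseudogene CHG was 47.7% and 46.5% (difference -1.17, SE 0.187), or a difference of -1.40 (SE 0.0522) with equal weights per cytosine. The pooled CHG difference was -1.57 in pericentromeric pseudogenes and 0.242 (interval -0.133 to 0.616) in those of the arms. These 2 groups were not run with equal weights, so the contrast between them rests on pooled levels. Pooled CG in pseudogenes of the arms was 1.13 points higher (SE 0.205), and over all pseudogenes the CG difference was -0.390 (SE 0.355), or -0.666 (SE 0.0347) with equal weights per cytosine. The 932 protein-coding genes methylated in both CG and CHG were like the pseudogenes, with CHH of 10.5% and 9.62% (difference -0.888, SE 0.0512). Protein-coding bodies as a whole had a CG level of 16.7% in the wild type and 16.8% in xrn3 (difference 0.0120, SE 0.0331). That difference was -0.400 (SE 0.0209) with equal weights per cytosine and -0.0688 (SE 0.0346) with at least 10 reads. Body-methylated genes, 5541 in number, had a CG level of 34.6% and 34.3% (difference -0.282, SE 0.0466), and 54.5% of them were lower in xrn3. Non-coding RNA genes had a higher pooled CG level in xrn3 (18.5% against 19.3%, difference 0.862, SE 0.345), which turned to -0.209 with equal weights.

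Regions downstream of genes, where XRN3 acts on RNA, had slightly less CHH methylation in xrn3. In the 1 kb downstream of the 3′ ends of 11384 genes with an inferred strand, CHH was 1.93% in the wild type and 1.86% in xrn3 (difference -0.0706, SE 0.0101, or -0.114 with equal weights per cytosine). The 1 kb upstream of the 5′ ends had a difference of -0.142 (2.71% against 2.57%, SE 0.0179). Downstream of 2520 genes with no other gene within 1 kb, the CHH difference was -0.340 (3.96% against 3.62%, SE 0.0325). For 1746 genes with a tandem neighbour within 1 kb it was -0.0274 (1.40% against 1.37%, SE 0.0154). For 1820 genes with a convergent neighbour within 1 kb it was -0.00886 (1.01% against 1.00%, SE 0.00933). Where a neighbour lay within 1 kb, that 1 kb reached into it. Beside convergent neighbours the wild-type CHH level was close to the chloroplast rate of 0.913%, so little could be lost. Beside tandem neighbours it lay further above that rate, which was not subtracted in either set. Pooled CG and CHG levels downstream were 0.155 (SE 0.0467) and 0.0953 points (SE 0.0141) higher in xrn3, and these changed sign with equal weights per cytosine (-0.233 and -0.0706). Where the convergent neighbour lay within 1 kb, the downstream CG level was lower in xrn3 (22.8% against 22.2%, difference -0.632, SE 0.142). The last 1 kb inside the same genes was lower too (difference -0.473, SE 0.145). Downstream of the genes with no other gene within 1 kb, pooled CG was 0.699 points higher in xrn3 (SE 0.0908). These genes alone were not run with equal weights per cytosine, so whether that difference would also change sign is not known.

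**Figure D2:**
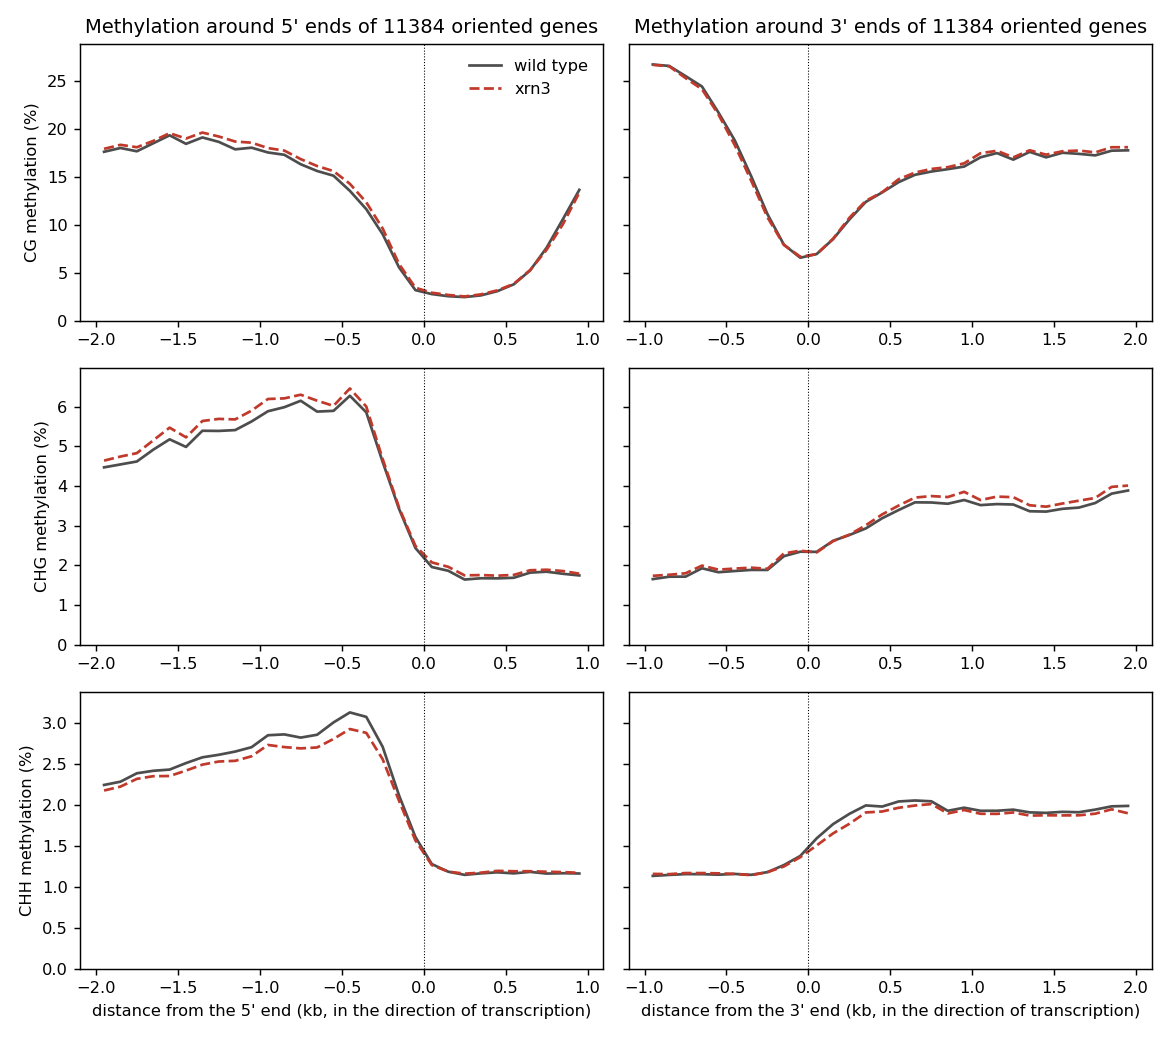
Pooled CG, CHG and CHH methylation in percent in 100 bp bins around the 5′ ends (left) and 3′ ends (right) of 11384 genes with an inferred strand, against distance in kb in the direction of transcription, for the wild-type (solid grey) and xrn3 (dashed red) libraries. The lines lie close together, with CHH lower in xrn3 outside the genes by at most 0.203 points in any bin.

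Differentially methylated windows went mostly one way in CHH and both ways in CG. Of 1184269 CHH windows, 3387 were called lower and 321 higher in xrn3. Called lower windows had a median level of 30.8% in the wild type and 15.4% in xrn3, on a median of 485 and 387 reads. In CG, 2572 of 677377 windows were called higher and 3380 lower, with medians of 4.07% and 64.9% in the first group and 65.2% and 3.49% in the second. CHG gave 144 higher and 237 lower of 733352 windows. With the size thresholds halved, 9019 CG windows were higher and 11960 lower, and 673 CHH windows were higher and 5297 lower, and an adjusted p under 0.001 left 2032 lower CHH windows. Windows called higher in CHG were also higher in CG, by 43.8 points over the 76 windows testable in both contexts, and windows called lower in CHH differed in CHG by -9.48 points. In pericentromeres lay 42.7% of the lower CHH windows and 23.4% of all CHH windows tested.

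Tests between the strands of 1 library gave 91 CG calls in the wild type and 66 in xrn3. Tests between the libraries on 1 strand each gave 5784 to 6270 calls over the same 673428 windows. In CHG the strands of 1 library gave 563 and 218 calls, more than the 176 and 169 calls between libraries on the same strand, so this control was not used as a measure of noise for CHG. The counts of called windows compare these 2 libraries only.

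**Figure D3:**
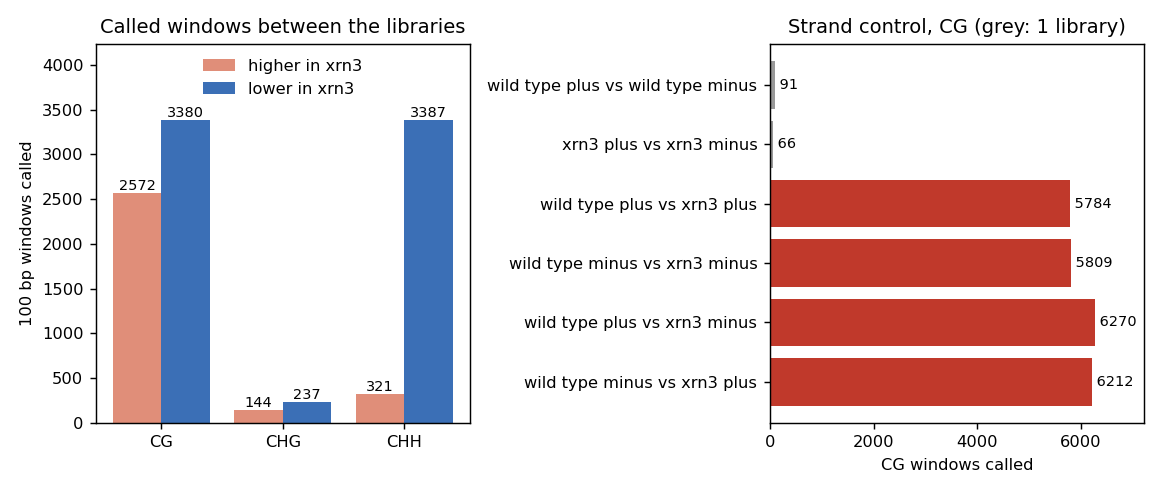
Left, number of 100 bp windows called higher (light red) or lower (blue) in xrn3 by context, as 2572 and 3380 in CG, 144 and 237 in CHG, and 321 and 3387 in CHH. Right, number of CG windows called between strands of 1 library (grey, 91 and 66) and between libraries on 1 strand each (red, 5784 to 6270), with 1 library per genotype.

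Called CG windows lay mainly in protein-coding genes, and CHH windows mainly outside genes. Protein-coding genes held 88.6% of the higher and 83.6% of the lower CG windows, against 57.7% of the windows tested. Only 7.65% of the lower CHH windows lay there, against 54.1% of those tested. The 1 kb downstream of 3′ ends held 269 of the 3387 lower CHH windows, 7.94% against 3.87% of windows tested (Fisher's exact test, two-sided, p = 2.3e-27). The higher CHH windows had a like share there (25 of 321, 7.79%, Fisher's exact test, two-sided, p = 0.0011). For the lower CHH windows, against windows of the same mean level, a background chosen after seeing the data, the expected share was 5.05%. The 1 kb upstream of 5′ ends held 11.3% of the lower and 10.9% of the higher CHH windows, against 5.01% of those tested. Flanks of genes of unknown strand held 22.0% of the lower CHH windows against 10.2% of those tested. Places outside genes and flanks held 43.5% against 16.7%, so the raised share was not particular to 3′ ends. CG windows were less frequent downstream of 3′ ends than among all windows tested, at 0.778% of the higher and 1.51% of the lower calls against 3.26%. For the lower CG windows the expected share was 1.32% among windows of the same mean level, below the observed share.

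Tests of whole gene bodies and flanks gave a small number of genes with large differences. In CHH, 656 of 113675 regions were lower and 35 higher in xrn3. CG gave 199 lower and 154 higher of 112917 regions, and CHG gave 173 lower and 118 higher of 112972. By region, 110 of 11384 upstream and 53 of 11384 downstream flanks with a known side were lower in CHH, as were 26 of 27438 protein-coding bodies and 38 of 4842 pseudogene bodies. The median region had 5387 CHH reads in the wild type and 4105 in xrn3.

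Some regions were methylated in the wild-type library and at background in xrn3. The body of AT1G64795 (chromosome 1, CG cytosines 24082593 to 24082758) had 87.1% CG, 52.6% CHG and 21.9% CHH in the wild type, and 0.342%, 0.840% and 0.555% in xrn3 (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.7e-282 for CG). AT1G75945 had 71.2% CG and 50.7% CHG in the wild type against 0.646% and 1.40% in xrn3. The flank of its neighbour SKP1 (AT1G75950), a subunit of SCF ubiquitin ligases, overlaps that gene and had 71.3% CG against 0.595%. Both lie on the chromosome arm of XRN3, within the same 1 Mb. The pseudogene AT3G22955 had 70.7% CG and 46.2% CHG against 0.901% and 0.472%, and the CHG level upstream of AT4G15050 was 46.6% against 1.69%. Among regions called lower in CHH, a flank of AT5G25240 had 36.9% against 24.6%, and a flank of SUV2 (AT5G45610), a gene of the DNA damage response, had 26.3% against 14.0%. The pseudogene AT1G57710 had 20.4% against 6.70% on 358 and 224 reads.

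Other regions were methylated in the xrn3 library alone or more strongly there. A flank of AT3G43970 had 11.2% CG and 1.32% CHG in the wild type, and 83.8% and 48.1% in xrn3 (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.2e-91 for CG). CG in a flank of AGL48 (AT2G40210), a MADS-box gene, was 7.35% against 75.8%, and in a flank of AT5G35405 it was 7.20% against 67.8%. The pseudogene AT1G61685 had 34.6% CG against 86.1%. The region upstream of NAC089 (AT5G22290), which encodes a NAC transcription factor, had 0.413% CHG against 43.8%, and the bodies of AT1G21928 and of the pseudogene AT2G32291 had 24.6% and 12.6% CHG against 53.6% and 45.6%. In CHH, a flank of AT5G20100 had 0.688% against 11.4%, and a flank of PKS1 (AT2G02950), which encodes a phytochrome kinase substrate, had 1.17% against 11.6%. The body of AT1G23650 had 11.01% CHH against 21.3%, and AT2G32291 had 3.78% against 12.1%.

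In the gene lists fixed beforehand, 4 of 656 regions were called, which needed an adjusted p under 0.01, the size threshold and the same sign on both strands. They belonged to 4 genes, all 4 were lower in xrn3, and the counts adjusted over the list alone were the same. By the adjusted p alone (Fisher's exact test, Benjamini-Hochberg), 10 regions were higher and 32 lower in xrn3, most of them below the size threshold. None of the 19 genes of the DNA methylation machinery had a called region, and 4 higher and 7 lower regions met the adjusted p alone. The largest differences in that list were in CG, upstream of VIM3 (50.1% against 64.2%), in the body of AGO4 (30.1% against 25.03%) and upstream of MET1, the maintenance CG methyltransferase (41.2% against 36.4%). The MET1 difference missed the limit of the adjusted p as well as the size threshold. None of the 14 sentinel loci had a called region, and those with the largest differences missed the size threshold, with CG in a flank of QQS at 42.5% against 27.5%, in a flank of AG at 12.6% against 2.87% and in the body of SDC at 8.47% against 12.9%. None of the 8 housekeeping genes had a called region, with UBQ10 at 11.04% against 18.2% CG downstream, TUA5 at 7.38% against 2.94% in the body and ACT7 at 10.7% against 14.8% upstream. Of these, UBQ10 and ACT7 missed the limit of the adjusted p too. Of 9 imprinted genes, MEA, a Polycomb gene, fell upstream of its 5′ end in CG from 22.2% to 1.36% (Fisher's exact test, Benjamini-Hochberg adjusted p = 4.6e-17). A flank of HDG9 had 69.3% CG against 79.8%, and CHG upstream of HDG3 was 12.2% against 7.03%, both short of the size threshold and of the adjusted p.

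Among 9 retrotransposons known to be active, a flank of EVD, a Copia element, fell in CHG from 37.3% to 22.1% (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.8e-06). A flank of the ONSEN copy AT1G58140 fell in CHH from 29.7% to 23.6% (Fisher's exact test, Benjamini-Hochberg adjusted p = 9.7e-08). Flanks of other ONSEN copies were not called, at 84.5% against 77.4% CG for AT3G59720 and 40.1% against 46.8% CHG for AT5G13205, which also missed the limit of the adjusted p. All 9 bodies were lower in CHH in xrn3, by between -2.57 and -0.446 points, without passing the size threshold, and their pooled level was 14.9% against 14.0%. Of 18 genes of transcription termination and RNA decay, PCFS4, a pre-mRNA cleavage factor, fell in CHH upstream of its 5′ end from 13.0% to 7.98% (Fisher's exact test, Benjamini-Hochberg adjusted p = 9.0e-12). FPA, which promotes 3′ end formation, had 49.5% against 36.7% CG downstream of its 3′ end, a flank of CSTF77 had 38.7% against 31.1% CG, and a flank of FCA had 41.9% against 48.6%, none past the size threshold. The FCA difference missed the limit of the adjusted p as well.

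Sequence differences between the lines were rare by the rule used. The opposite strand showed a candidate change at 1 cytosine in xrn3 and at 3 in the wild type. Coverage of 118973 windows of 1 kb gave 0 runs that differed by a log2 ratio beyond 1 in either direction, with a standard deviation of 0.14 on the log2 scale. Because the tables leave out cytosines with no G on the opposite strand, the rule misses complete changes. Between covered neighbours, 222 cytosines were absent from the xrn3 table alone and 70 from the wild-type table alone. Low depth could also leave a site absent, so these need not be sequence changes.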

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

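The chloroplast rate, equal weights per cytosine and calls between strands were planned analyses. Their use as tests of explanations, with limits, was chosen only after the results had been seen. The test of windows near candidate changed cytosines was also chosen then. The tests by thinning, by equal coverage and by leaving out altered cytosines had their predictions written before they were run.

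The mitochondrial genome, which the comparisons do not use, carried unconverted reads far above the chloroplast level. In the wild-type library 14.4% of CG, 8.59% of CHG and 2.56% of CHH reads were unconverted. In the xrn3 library the shares were 11.4%, 6.78% and 2.13%. Mitochondrial CG sites had 64.61 reads per site in the wild type and 63.99 in xrn3, of which 9.32 and 7.26 were unconverted. Mean depth at nuclear CG sites was 23.3 and 17.8 reads. Unconverted mitochondrial reads were thus lower in xrn3 together with nuclear depth, as reads from nuclear copies of mitochondrial DNA would be. The lower shares in xrn3 are therefore not evidence of less mitochondrial methylation. Reads from nuclear copies were not separated, and no explanation was tested.

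CHH methylation was lower in the xrn3 library. Incomplete conversion would need a lower chloroplast rate in xrn3, but that rate was 0.0259 points higher. Pericentromeric 1 kb windows of nearly equal scaled coverage gave -0.947 points, which argues against uneven coverage. Thinning the wild-type library gave -0.904 points, but taking reads away at random leaves a pooled level in place, so this decided nothing about depth. With 1 library per genotype, an effect of xrn3 and a difference between plants or library preparations cannot be told apart.

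The higher pooled CG and CHG levels likely came from a larger share of xrn3 reads in densely methylated regions. With every cytosine weighted equally, the CG difference was -0.319 points, under the limit set for that explanation. No biological explanation was tested.

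CG windows differed in both directions inside protein-coding genes, and 56.8% of 5952 calls were lower in xrn3. Counting noise is an unlikely source, since the most calls between strands of 1 library came to 1.57% of the fewest between libraries. A cytosine changed fully to T in 1 line is not listed for that line, so it entered no window. Of 296 candidate sites for such changes, 222 were not listed for xrn3 and 70 not for the wild type. No changed base was seen at the unlisted sites, and low depth could also leave a site unlisted. Of nuclear cytosines, 99.79% had reads in xrn3 and 99.92% in the wild type. Of the calls, 3 (0.0504%) lay in or within 100 bp of a candidate site, against 0.0540% of windows tested. This share cannot show whether changed cytosines were read as unmethylated, since unlisted ones add no reads. Without cytosines that showed under 90% G opposite, 99.6% of the calls were left. Cytosines changed in part are therefore an unlikely source of most calls. Sequence differences that act on methylation in other ways were not tested. With 1 line per genotype, an effect of xrn3 and CG differences gained in lines kept apart for generations cannot be told apart.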

How the results depend on the processing

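The background with room for the difference, the background matched on mean level and the count of sites absent from 1 table were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library and the labels carry no replicate numbers. With 1 library per group, leaving out a library and other splits of the samples were also impossible.

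Of 78 values of the main levels under the alternatives, 38 stayed within the counting interval, 31 moved in the same direction and 9 changed sign. Of 42 values for the other levels, 26 stayed, 10 moved and 6 changed sign. The CHH difference stayed negative for the genome, pericentromeres, arms and pseudogenes under the 6 alternatives run for them. Downstream of genes it stayed negative under the 4 run there (at least 1 or 10 reads, equal weights, no other gene within 1 kb). Of 60 window counts 51, of 36 gene region counts 32, of 6 variant counts 4 and of 4 coverage counts 4 stayed within 1.5 times the reported count. Of 30 window locations 25, and of 144 values for named gene regions 143, kept their direction and side of the threshold.

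With equal weights per cytosine, the differences in CG, CHG and CHH were -0.319, -0.330 and -0.311 points for the genome, -0.604, -1.27 and -0.956 for pericentromeres, -0.232, -0.0632 and -0.109 for arms, and -0.233, -0.0706 and -0.114 downstream of 3′ ends. They were -0.400, -0.0162 and -0.0189 for protein-coding bodies, -0.209 (CG) and -0.116 (CHG) for non-coding RNA genes and -0.956 (CHH) for pseudogenes. By construction, this alternative takes away the extra weight of deeply covered cytosines.

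With at least 10 reads, they were 0.481, 0.105 and -0.246 for the genome, -0.502, -1.11 and -0.947 for pericentromeres, 0.170, 0.136 and -0.0604 for arms, and 0.0951, 0.0704 and -0.0827 downstream of 3′ ends. Protein-coding bodies then gave -0.0688 (CG) and -0.00352 (CHH), a change of sign, and pseudogenes -0.950 (CHH). With at least 1 read, the genome gave 0.690, 0.223 and -0.207, the arms 0.271 (CG) and protein-coding bodies 0.0277 (CG). With the chloroplast rate subtracted, CHH differences were -0.238 for the genome, -0.937 for pericentromeres, -0.0750 for arms, -0.948 for pseudogenes and -0.0254 for protein-coding bodies, which changed sign. For genes with no other gene within 1 kb downstream, the pooled differences downstream were 0.699 (CG), -0.00709 (CHG, a change of sign) and -0.340 (CHH). For these alternatives the cause was not tested.

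Halved size thresholds gave 9019 higher and 11960 lower CG windows and 673 higher and 5297 lower CHH windows. Windows of 200 bp gave 1025 and 1436 in CG and 113 and 1765 in CHH, with fewer windows tested. An adjusted p under 0.001 left 2032 lower CHH windows. Flanks of 500 bp gave 274 higher and 367 lower gene regions in CG and 69 and 1119 in CHH, and the cause was not tested. Sites absent from 1 table numbered 222 for xrn3 and 70 for the wild type.

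The share of lower CG windows downstream of 3′ ends, 1.51%, was above the background with room for the difference (1.45%, Fisher's exact test, p = 0.77) and the matched background (1.32%), a change of direction. The share of lower CHG windows was 1.27% in the 500 bp downstream (Fisher's exact test, p = 1), a change of direction, and its share of 3.797% in 1 kb passed the threshold against windows with room (1.60%, p = 0.015). Higher CHH windows no longer passed in the 500 bp downstream (2.80%, Fisher's exact test, p = 0.58). The cause was not tested. The CG difference in the body of AT3G22955 was -51.9 points with at least 10 reads and no longer passed all criteria.

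The call criteria at this depth limit what the CHG and CHH windows can show. On simulated data at the real depth, 54.4% of CHG windows with a true difference of 25 points and 73.5% of CHH windows with 12.5 points were recovered, so differences near the size thresholds were missed in part.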

Other observations

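The window measure of coverage at XRN3 and its test were chosen only after the coverage had been seen, and the CHG and CHH counts around XRN3 only after the CG result. The CG test on the interval around XRN3 and the test on following bases had their predictions written before they were run. For the following bases, chloroplast rates for each group of sites replaced a single rate after the first result had been seen, and the direction of the result was the same.

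In 1 Mb blocks, the lowest CG and CHG differences both lay at 3 to 4 Mb of chromosome 2, at -5.86 points (47.5% against 41.6%) and -3.92 points (27.0% against 23.1%). The blocks on either side had 73.4% and 80.8% CG in the wild type, with differences of -0.0281 and -0.341 points. The block is part of the pooled pericentromeric levels. In pericentromeric 1 kb windows with a log2 ratio of scaled coverage of at least 0.2 (higher in xrn3), CG differed by -2.34 points (SE 1.60). At nearly equal coverage it differed by -0.304 points (SE 0.0784). Whether the first windows lay in this block was not tested. Whether reads from elsewhere, including the mitochondrial genome, mapped to the block was not tested either. Its difference is therefore not taken as a loss of methylation. The lowest CHH difference lay at 13 to 14 Mb of chromosome 3, at -1.33 points (12.1% against 10.8%).

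The xrn3 allele might have brought along a chromosome interval from another line, which could raise the number of called CG windows around XRN3. In the 1 Mb around the gene, 18 windows were higher and 42 lower of 5804 tested, or 1.03% against a median of 0.937%. Of 1143 such intervals, 31.2% had as large a share in CG, 7.17% in CHG and 51.9% in CHH. The CG share was thus not unusually high. It cannot show whether an interval came with the allele, since one with the usual share of calls would look the same. All 9 called CHG windows there were lower in xrn3 and lay at AT1G75945 and SKP1, and whether this locus was inherited with the allele was not tested.

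The drop in coverage near the lower-coordinate end of XRN3 in the xrn3 library could be chance. A 100 bp window as low occurred in 295 of 27444 protein-coding genes (1.07%), under the limit of 5% set for chance, and in 9 of 498 genes at least as long as XRN3 (1.81%). An inserted sequence at this place is a hypothesis that was not tested.

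A weaker CMT2 pathway could lower CHH methylation most, in relative terms, at sites followed by A or T in both positions, which include the sites CMT2 prefers. The chloroplast rate of each group of sites was subtracted first, at 0.922% and 0.941% for such sites and 0.840% and 0.891% with C first (wild type and xrn3). In pericentromeres the relative change was then -10.1% at such sites and -16.9% at sites with C first. The difference of 6.78 percentage points (SE 0.276) was opposite to the hypothesis. Its SE leaves out the error of the subtracted rates. The subtracted rate differed more between the libraries at sites with C first, which enlarged the relative fall there. Part of the difference therefore comes from the subtraction, and how large that part is was not worked out. On the scale of points the order was the other way, with 11.7% against 10.5% at sites followed by A or T and 2.66% against 2.21% at sites with C first. In the arms the relative changes were -5.11% and -14.0%. There the corrected level at sites with C first (0.703% and 0.605%) lay below the rate subtracted.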
